A study of Mus musculus with 4 samples.

How the data were processed

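Poly(A)-selected RNA of mouse colon tumour cells grown in RPMI medium was sequenced for 4 samples, the control cells and 1 sample each of the mutant lines M8, M32 and M83, made with ENU (N-ethyl-N-nitrosourea), an alkylating agent that leaves mainly point mutations. RNA was extracted with RNeasy Micro columns, libraries were made with the NEBNext Poly(A) module and the NEBNext Ultra II kit, and sequencing was on an Illumina NextSeq, per the labels' protocols. The labels speak of triplicates, while the table used here holds 1 column per sample, so whether a column sums repeats is unknown. Each column is called a library here. The authors deposited raw counts per gene as whole numbers, with no normalisation. The genome build was GRCm38, per the submitters' processing notes. The aligner, the counting tool, the annotation, the strand setting and the name of the cell line are not given in the sources used here. Whether the mutant lines came from the same culture as the control is not given either, so a difference from control may be one of parent culture. Without a stated strand setting, reads of overlapping genes on opposite strands cannot be told apart.

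The table has 41457 rows, of which 20208 had no count in any library. Symbols were taken from the table, and chromosome positions from GENCODE vM21, which uses the same build and contains 41434 of the row identifiers. The report gives the total count of each library. A count of 0 allows up to 3 counts, which is 0.118 CPM (counts scaled to a common library size) in control and 0.104 CPM in M83. Intervals and floors cover counting error only, since the reads carry no molecular identifiers. The TMM factors of edgeR lay between 0.986 (M8) and 1.03 (M83), and scaling by library size alone moved log2 values by less than 0.1 in every library.

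The labels give the 3 mutant lines 1 genotype label, and the main comparison set them against the control with edgeR's quasi-likelihood F-test (edgeR 4.0.16, R 4.3.3, TMM factors, filterByExpr, 13576 genes tested, Benjamini-Hochberg adjusted p under 0.05). This fit has 2 residual degrees of freedom. The lines are different mutants, so the p-values measure only the spread between these mutant lines, and the lone control is assumed to vary like them. The labels do not say whether the triplicates were separate cultures, and no repeat is available as a column of its own. DESeq2 1.42.0 was the alternative tool. Each line was also set against control without a test, by a rule of size. A gene counted when its TMM-normalised log2 ratio (prior count 2) was at least 2 in size, the higher of both libraries held at least 50 counts, and the exact 95% binomial (Clopper-Pearson) interval of the ratio left out 2-fold. A gene was called set apart in a library when it lay at least 4-fold above, or at least 4-fold below, every other library, with at least 50 counts in the highest.

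There were 27 fixed gene lists, covering interferon response, antigen presentation, checkpoint ligands, cytokines, NF-kB, Wnt, epithelial, mesenchymal and intestinal identity, p53, DNA repair, cell cycle, MAPK, hypoxia, stress responses, cholesterol, NRF2, YAP, TGF-beta, mitochondrial, germline and imprinted genes, 4 sets of markers of other cell types, and 16 genes named regardless of value. The 26 lists with at least 5 tested members were tested with camera (limma 3.58.1) with a preset correlation of 0.01 between genes. Camera with an estimated correlation and fry stand beside it. For single lines, a list's median log2 ratio was ranked among 10000 random lists of the same size matched on mean expression. The lists, the tests, the alternatives and the rule for naming genes were fixed before the data were examined. The rule named 10 genes per direction for the main comparison, those that passed first and then those with the smallest p (mean CPM of at least 5, same direction in the 3 lines). It also named up to 4 members per list, the 6 most changed genes per direction in each line, the 4 genes per direction furthest set apart in each line, and the 16 fixed genes. Not every gene that this rule named is reported here. Genes without a symbol were counted and passed over in naming, and other genes were chosen after their values were seen. These were Vim, Col1a2, Cdh1, Epcam, Cdx2, Ptprc, Pecam1, Irf7, Ifi27l2a, mt-Rnr2, the neighbours of E2f6, the keratins beside Krt6a and the genes shared by the 3 lines.

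The scripts were tested on simulated data drawn from the real means, library sizes and dispersions of single genes, and this replaced a first run that had used trended dispersions. For ENU lines against control, the quasi-likelihood test on 13195 genes recovered 12% of the genes changed 2-fold, 74% at 4-fold, 98% at 8-fold and 94% at 16-fold, with 13 false calls. These shares hold for 50 genes changed at each fold. With fewer changed genes the adjustment is stricter, so recovery in the real data may be lower. For 1 mutant line against control, counts were drawn with counting noise only, without those dispersions. There the rule of size on 13576 genes recovered 0% at 2-fold, 54% at 4-fold, 100% at 8-fold and 98% at 16-fold, with 0 false calls. False calls from the spread between cultures were therefore not measured. Of 20 lists changed 1.5-fold, camera with the preset correlation recovered 20, camera with an estimated correlation 0 and fry 4, each with 0 false calls among 80 unchanged lists. Genes were drawn independently of each other there, so false calls from correlated genes were not measured. Overlaps between lines were set beside 100 simulations in which all libraries were drawn from 1 common mean and the lines shared 1 drawn control. Their spread was that fitted between the mutant lines, so real differences between lines entered as noise. The real control library cannot be split. The share of each named gene's sequence that other genes also contain was measured in words of 50 bases, in either orientation, and genes with a large share are uncertain. Alternatives tried were other scalings, filters, tools, thresholds and prior counts, and leaving out each mutant line.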

Results

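Gene expression was compared between control cells of a mouse colon tumour line and 3 ENU mutant lines, M8, M32 and M83, with 1 column of poly(A) RNA counts each, called a library here. The total count was 25818148 in control, 28879954 in M8, 27312207 in M32 and 28011773 in M83, and between 16712 (control) and 17691 (M83) genes had a count. Across the 13576 tested genes, which are not independent replicates, Pearson's correlation of log2 CPM ranged from 0.962 (M8 with M83) to 0.972 (control with M32). Values of single lines have no replicate check, and differences between them are given as higher or lower.

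The transcript profile of the 4 libraries was rich in mesenchymal genes. Vim, which encodes the intermediate filament vimentin, had 115473 counts in control and 124169, 129869 and 146659 in M8, M32 and M83. Col1a2, a fibrillar collagen gene, had 43464 counts in control and 52481, 51697 and 43937 in the lines. The epithelial adhesion gene Cdh1 had 4 counts in control, 2 in M8 and 0 in M32 and M83. Epcam and the intestinal transcription factor gene Cdx2 had 0 counts in every library, which allows up to 0.118 CPM in control. Of the 39 listed epithelial genes only 13 reached the filter on low counts, and of the 47 colonic and intestinal differentiation genes 11. Krt20, a keratin of differentiated gut epithelium, was an exception with 1914 counts in control and 3306, 1008 and 3667 in M8, M32 and M83. Among the leukocyte markers 5 of 28 were tested, and Ptprc, the pan-leukocyte marker, had at most 4 counts. Cd8a, a T-cell co-receptor gene, nevertheless had 4353 counts in control and 3083, 4558 and 5163 in the lines.

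The first comparison asked which genes differed from control in the 3 mutant lines alike. Slc1a2, which encodes a glutamate transporter of the plasma membrane, lay almost at the floor in all of them, and it was the only gene that passed. With a lone control, a loss in the lines cannot be told from a gain in the control culture. As to its values, Slc1a2 was far above the floor in control. The gene had 2002 counts in control and 10, 5 and 12 in M8, M32 and M83, a mean of 0.317 CPM ± 0.119 (SD, n = 3) in the lines against 78.5 CPM in control. The log2 fold change was -7.92 (SE 0.354, edgeR quasi-likelihood adjusted p = 0.00259). The gene (ENSMUSG00000005089) spans positions 102658659 to 102790784 of chromosome 2 on the plus strand in GRCm38 and is protein-coding. At an unadjusted p under 0.05 edgeR listed 448 genes, 380 higher and 68 lower in the lines, where 678.8 would be listed by chance. DESeq2, which tested 19529 genes on the same counts, called 37 genes, 33 up and 4 down.

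Among the 10 genes named as higher in the lines, none passed in edgeR, and all 10 were among the DESeq2 calls. Clic5, a chloride intracellular channel gene, had 46 counts in control and 473, 509 and 593 in M8, M32 and M83, a log2 difference of 3.37 (SE 0.364, edgeR adjusted p = 0.248). Cryab, a small heat shock protein gene, had 285 counts in control and 1475, 1313 and 1898 in the lines, with a log2 difference of 2.31 (SE 0.306, edgeR adjusted p = 0.624). Aldh1a1, a retinaldehyde dehydrogenase gene, had 20 counts in control and 539, 594 and 210 in the lines. Thbs1, which encodes the matrix protein thrombospondin, had 1683 counts in control and 7757, 15903 and 9884 in the lines. Il1rl1, the gene of the interleukin-33 receptor ST2, had 1986 counts in control and 8827, 6592 and 11965 in the lines. Igf2r, the mannose-6-phosphate receptor gene, had 969 counts in control and 5136, 4008 and 3079 in the lines. Tenm4 and Ces2g had log2 differences of 3.03 (SE 0.463) and 2.38 (SE 0.441), and Sertad4 had 269 counts in control and 995, 1022 and 1090 in the lines. Cryab shares part of its sequence with the neighbouring gene Hspb2.

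Besides Slc1a2, 8 genes named as lower in the lines passed in neither tool. Acadm, the medium-chain acyl-CoA dehydrogenase gene of fatty acid oxidation, had 2289 counts in control and 1178, 939 and 1516 in M8, M32 and M83 (edgeR adjusted p = 1). The remaining log2 differences were -1.13 (SE 0.347) for Rabggtb, -1.24 (SE 0.351) for Hist1h2ap, -0.80 (SE 0.228) for Mettl14, a subunit of the RNA m6A methyltransferase, -0.73 (SE 0.203) for Rpl34, -0.63 (SE 0.201) for Dnttip2, -0.72 (SE 0.231) for Fastk and -0.65 (SE 0.21) for Smarca4, a chromatin remodelling ATPase. Hist1h2ap is uncertain, because 93.1% of its words occur in another histone gene, and Fastk shares 28.5% with the overlapping gene Slc4a2. Ppef1, a protein phosphatase gene below the expression limit of this rule, had 259 counts in control and 6, 12 and 6 in the lines. It missed the threshold (log2 difference -5.13, SE 0.557, edgeR adjusted p = 0.248) and was the only other gene to pass when the filter on low counts was removed.

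**Figure D1:**
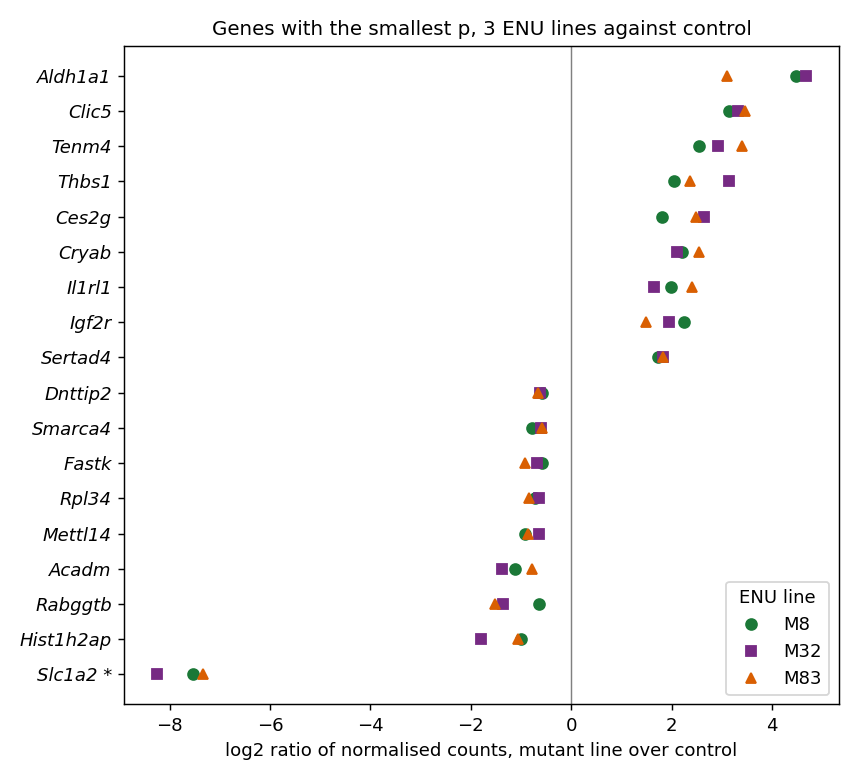
Log2 ratio of normalised counts of each mutant line over control (x axis) for 18 genes named in the comparison of the 3 lines with control (y axis), 1 point per line and no error bars because each line has 1 column of counts. The asterisk marks Slc1a2, the only gene past the threshold, with log2 ratios of -7.53, -8.26 and -7.33 in M8, M32 and M83.

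Proliferation genes were lower in the mutant lines as a group. In the cell cycle list 37 of 46 genes lay below control in every line, where 25% would do so by chance if the 4 libraries were exchangeable. These genes are correlated (estimated correlation 0.147) and share 1 control library, so they are not independent draws. In edgeR 0 passed singly, whether adjusted over all genes or adjusted over the list alone. Mki67, the proliferation marker, had 12301 counts in control and 5339, 8200 and 8746 in M8, M32 and M83. Rrm2, a ribonucleotide reductase subunit gene, had 10866 counts in control and 4921, 8413 and 8027 in the lines. It lies on chromosome 12, whose genes had a median log2 ratio of -0.55 in M8, so its value there may not be one of proliferation alone. Mybl2 had a log2 difference of -0.53 (SE 0.22). The list's median log2 difference was -0.31, and camera with the preset correlation gave an adjusted p of 6.38e-09, against an adjusted p of 0.475 with an estimated correlation. DNA repair genes fell as a list in the same test (median -0.24, 31 of 54 below control in every line, adjusted p = 0.000228, and 0.451 with an estimated correlation), with Pms2, a mismatch repair gene, at -0.50 and Rad54l, a recombination gene, at -0.50. MAPK/ERK output genes fell in this test mainly through M32 (median -0.24, 12 of 30 below control in every line, adjusted p = 9e-04, and 0.765 with an estimated correlation), with the immediate early genes Egr1 at -1.41 and Egr2 at -1.42. The list's median was -0.06 in M8, -0.69 in M32 and -0.11 in M83, and without M32 its adjusted p was 0.162.

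The mesenchymal list rose in camera with the preset correlation, though not in all of its genes. In it 18 of 35 genes lay above control in every line and 5 below, and 3 passed when adjusted over the list alone, against 0 when adjusted over all genes. Col1a1 had 10970 counts in control and 25288, 33405 and 32552 in M8, M32 and M83 (log2 difference 1.33, SE 0.27), Col6a2 161 counts in control and 725, 940 and 544 in the lines, and Acta2, the smooth muscle actin gene, 6 counts in control and 199, 474 and 53. Camera gave the list an adjusted p of 0.000274, and an adjusted p of 0.475 with an estimated correlation. The TGF-beta and BMP list rose in the same test (15 of 26 above control in every line, 1 passed when adjusted over the list alone, adjusted p = 0.000625, and 0.451 with an estimated correlation), with Thbs1 named above and Inhba, the activin A gene, at 0.71 (SE 0.222). The fibroblast marker list, which shares the collagen genes with the mesenchymal list, rose as well (8 of 14 above control in every line, 1 passed when adjusted over the list alone, adjusted p = 0.000483, and 0.451 with an estimated correlation). In that list Mfap5 had 15 counts in control and 102, 57 and 62 in the lines, while Col1a2 was nearly level and Serpinf1 had 508 counts in control and 1390, 2587 and 203 in the lines.

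The p53 target list (median 0.24, adjusted p = 0.0364), the YAP/TEAD and fetal intestinal list (median 0.24, adjusted p = 0.0385) and 6 tested endothelial markers (median 0.93, adjusted p = 0.0154) also rose in camera with the preset correlation. With an estimated correlation their adjusted p was 0.569, 0.765 and 0.475. Trp53inp1, a p53-induced gene, had a log2 difference of 1.03 and Dcxr 1.17, and Clu, a marker of the fetal-like intestinal state, had 125 counts in control and 323, 548 and 624 in M8, M32 and M83. The endothelial members were weakly expressed, with Eng at 97 counts and Flt1 at 59 counts in control and Pecam1 at 5, and this was the only list that passed in fry (adjusted p = 0.0381). Its median in single lines lay within the matched random lists, at percentile 88.9 in M8, 71.0 in M32 and 59.6 in M83. The p53 list no longer passed without M8 (adjusted p = 0.0691), and the YAP/TEAD list no longer passed without M32 (0.197) or M83 (0.108). With no filter on low counts 6 lists passed, and the p53 (0.0989), YAP/TEAD (0.14) and endothelial (0.152) lists were lost. In all, 9 of the 26 lists passed with the preset correlation, 0 with an estimated correlation (smallest adjusted p 0.451) and 1 in fry.

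The other 17 lists did not pass. Their adjusted p in camera with the preset correlation was 0.057 for cholesterol biosynthesis, 0.063 for MHC class I antigen presentation, 0.08 for checkpoint and NK-cell receptor ligands, 0.197 for hypoxia and glycolysis, 0.266 for NRF2, 0.404 for chemokines and cytokines, 0.43 for type I interferon-stimulated genes, 0.443 for epithelial genes and 0.484 for the unfolded protein and integrated stress responses. For interferon gamma-responsive genes it was 0.507, for mitochondrially encoded genes 0.521, for leukocyte markers 0.551, for colonic differentiation 0.697, for germline and imprinted genes 0.697, for Wnt targets 0.802, for NF-kB targets 0.805 and for the 16 genes named regardless of value 0.802. Both interferon lists and the mitochondrial list had a positive median (0.25, 0.12 and 0.01) and mean beside a downward test. The median and mean were taken over edgeR's fitted log2 differences, while the test used log2 CPM, so their signs can differ. The type I list's mean log2 ratio was -2.06 in M8, 0.57 in M32 and 0.87 in M83. Without M8 the type I interferon list was higher in the other lines, with an adjusted p of 1.84e-07, and the MHC class I list passed as well (0.0122). Without M83 the cholesterol list passed (8.45e-11). These calls used the preset correlation, and an estimated one, tried only with all lines, gave 0.87, 0.733 and 0.87. Only 1 of 12 erythroid and muscle markers was tested, too few for a list test.

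The 16 genes named regardless of value, drivers of colorectal cancer and genes of antigen presentation, had an edgeR adjusted p of 1 each. Apc had 2890 counts in control and 2896, 3520 and 3688 in M8, M32 and M83 (log2 difference 0.08, SE 0.242), and Trp53 had 4723 counts in control and 4603, 4253 and 4387 in the lines (-0.24, SE 0.206). The MHC class I heavy chain genes H2-K1 and H2-D1 had log2 differences of 0.53 (SE 0.279) and 0.35 (SE 0.299), and B2m, the light chain gene, had 8725 counts in control and 7024, 7269 and 13202 in the lines. Cd274, which encodes the checkpoint ligand PD-L1, had 41 counts in control and 9, 29 and 79, a log2 ratio of -2.11 in M8. The log2 differences of Jak2, Braf, Arid1a, Pik3ca, Jak1, Smad4, Ctnnb1 and Fbxw7 lay between -0.23 (Arid1a) and 0.39 (Jak2).

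**Figure D2:**
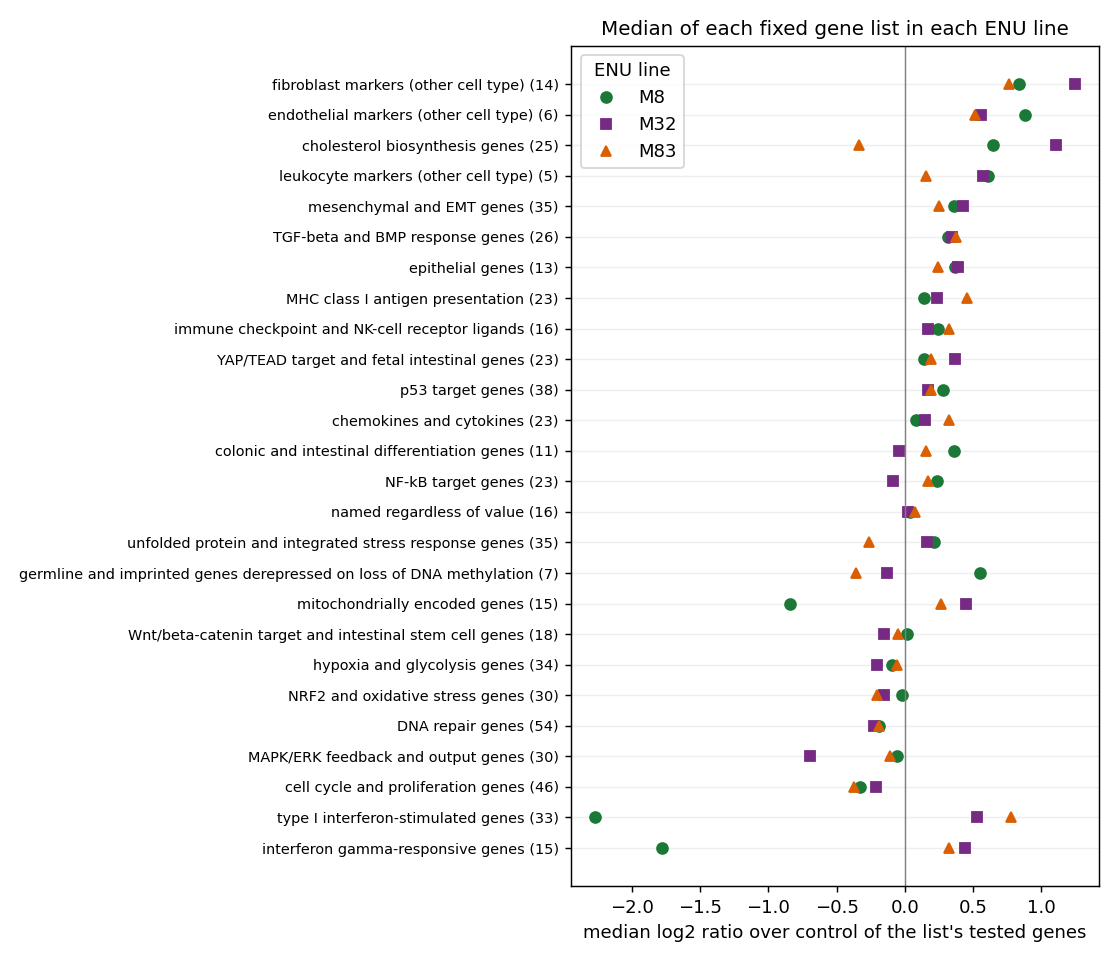
Median log2 ratio over control (x axis) of the tested genes of each fixed list (y axis, number of genes in parentheses), 1 point per mutant line. The type I interferon list sits at -2.27 in M8 against 0.53 and 0.78 in M32 and M83, and the cholesterol list at 1.11 in M32 against -0.34 in M83.

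Each mutant line was then set against control on its own. In M8, genes of the interferon response were far lower. The type I interferon-stimulated list had a median log2 ratio of -2.27, below each of 10000 matched random lists, with 32 of 33 genes lower and 14 meeting the 4-fold rule. The same list was higher in M32 (median 0.53, 27 of 33 genes higher) and in M83 (median 0.78, 31 of 33 higher). Oas2, an antiviral oligoadenylate synthetase gene, had 346 counts in control, 14 in M8, 340 in M32 and 674 in M83. Irf7, an interferon regulatory factor gene, had 220, 31, 249 and 811 counts, and Ifi27l2a 114, 6, 151 and 222 counts in the same order. The interferon gamma list had a median of -1.78 in M8, with 14 of 15 genes lower. In it, Gbp7, a guanylate-binding protein gene, had 201 counts in control, 4 in M8, 139 in M32 and 183 in M83, and Irgm2 138, 12, 254 and 439. Gbp7 shares 12.8% of its words with other genes.

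E2f6, a transcriptional repressor gene of the E2F family, was nearly lost in M8. It had 369 counts in control, 6 in M8, 403 in M32 and 549 in M83, a ratio of 0.0195 in M8 over control (95% exact interval 0.00531 to 0.032). The gene lies on chromosome 12 from 16810963 to 16839742 on the plus strand. The genes of chromosome 12 had a median log2 ratio of -0.55 in M8, and the neighbours Rock2 and Pqlc3 were at -0.77 and -0.75. Acot1 on the same chromosome had 122 counts in control and 4 in M8, and 18.9% of its words occur elsewhere, mostly in Acot2. Transcripts of the mitochondrial genome were lower in M8, with a median of -0.84 and 14 of 15 genes lower, and took 1.27% of its counts against 2.36% in control. mt-Nd2 was at -1.70, mt-Cytb at -1.32 and the ribosomal RNA mt-Rnr2 at 0.26. The long noncoding RNA Tslrn1 had 0 counts in control and 126 in M8, and the lipase gene Lipo3 had 0 and 100. In all, 86 genes were higher and 61 lower in M8 by the rule.

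In M32, cholesterol synthesis genes were higher. The list had a median of 1.11, above each random list, with 22 of 25 genes higher and 15 at least 2-fold higher. In M8 the median was 0.65, with 23 of 25 higher, and in M83 it was -0.34, with 21 of 25 lower. Fdps, the farnesyl diphosphate synthase gene, had 1693 counts in control, 4249 in M8, 6053 in M32 and 1059 in M83. Insig1, the sterol-sensing regulator gene, had 558, 1429, 2278 and 800, and Idi1 1013, 2745, 2219 and 503, with 30.5% of its words found elsewhere. MAPK/ERK output genes were lower in M32 (median -0.69, 26 of 30 lower, below each random list). Egr1 had 18871 counts in control, 8137 in M8, 3253 in M32 and 12461 in M83, Egr3 240, 292, 47 and 258, and the EGF receptor ligand gene Areg 637, 685, 146 and 536. Ablim1, an actin-binding protein gene, had 0 counts in control, 26 in M8, 316 in M32 and 0 in M83. Arhgap28 had 2, 32, 256 and 2, and the small leucine-rich proteoglycan genes Fmod and Prelp had 4, 50, 202 and 1 and 49, 590, 1751 and 196. Gpr141 had 142 counts in control, 133 in M8, 0 in M32 and 4 in M83. By the rule 123 genes were higher and 30 lower in M32.

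In M83, Scara5, a ferritin receptor gene, had 380 counts against 12 in control, 24 in M8 and 51 in M32, and Ces1f, a carboxylesterase gene, 921 against 32, 107 and 4. The keratin gene Krt6a had 62 counts in M83, 2 in control and 0 in M8 and M32, and 57.5% of its words occur in other genes. Single keratin genes chosen after their values were seen had 28, 2, 4 and 160 counts (Krt5), 9, 2, 3 and 71 (Krt16) and 11, 0, 3 and 89 (Krt17) in control, M8, M32 and M83. Keratins were not tested as a group, and 0 of the 13 tested genes of the epithelial list met the 4-fold rule in M83. Pakap had 235 counts in M83 and 0 in the other libraries, and it is uncertain, because 99.4% of its words occur in other genes, 90.9% in Akap2. Dppa4, a pluripotency-associated gene, had 185 counts in control, 518 in M8, 518 in M32 and 4 in M83, and lies on chromosome 16, whose genes had a median of -0.56 in M83, and 35.9% of its words occur elsewhere. Lefty1, a nodal antagonist gene, had 78 counts in control and 0 in M83. The median of the unfolded protein and integrated stress list was -0.26 in M83, with Asns at -1.31, against 0.21 in M8 and 0.16 in M32. By the rule 118 genes were higher and 30 lower in M83.

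**Figure D3:**
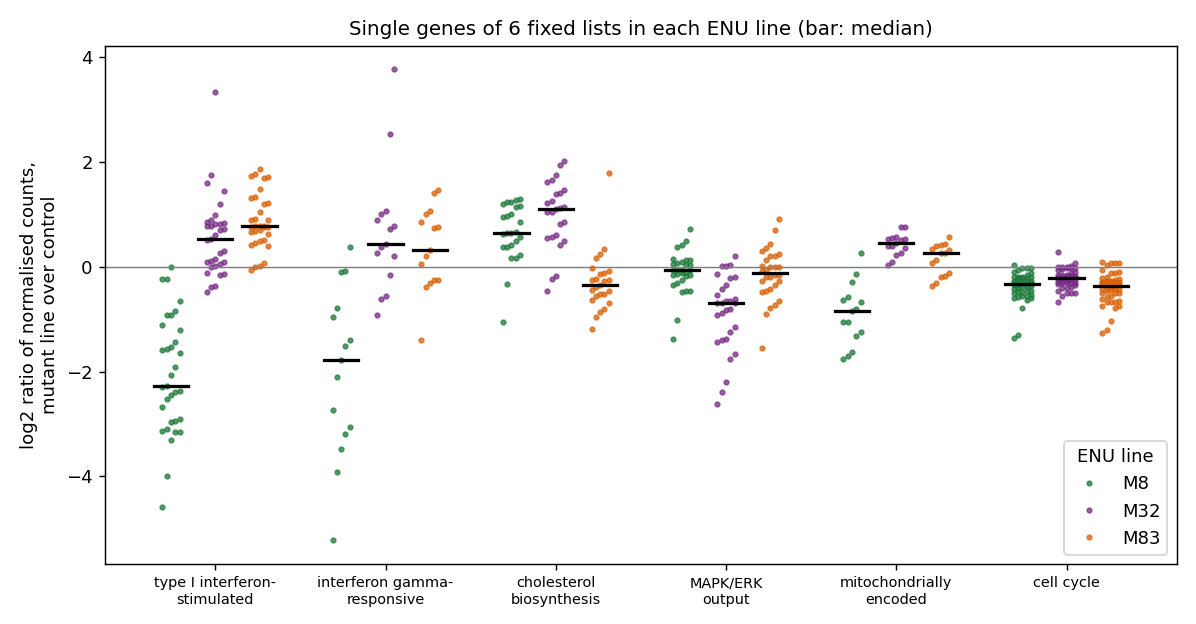
Log2 ratio of normalised counts over control (y axis) of every tested gene of 6 fixed lists (x axis) in each mutant line, with the median as a black bar. Interferon genes of M8 reach down to -5.22 (Gbp7), MAPK/ERK genes of M32 to -2.62 (Egr1), and cholesterol genes lie mostly above control in M8 and M32 and mostly below it in M83.

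The lines shared part of their differences from the common control. By the 4-fold rule 11 genes were higher in all 3 lines (Acta2, Aldh1a1, Aldh1a7, Serpinb8, Clic5, Crybg2, Tenm4, Slc22a18, Thbs1, Crabp2 and Cryab) and 4 lower, among them Slc1a2, Ppef1 and Adam8. Simulations drew unchanged lines and 1 shared control from a common mean, with the spread between the real lines as noise. In them 6.45 genes higher (at most 14) and 4.69 lower (at most 10) were shared by 3 lines. M8 and M32 shared 31 genes higher and 9 lower, M8 and M83 24 and 6, and M32 and M83 30 and 6, and 0 genes went opposite ways in any pair. The simulations gave means of 15.2 higher and 11.4 lower for M8 and M32, 14.4 and 11.8 for M8 and M83, and 14.4 and 11.9 for M32 and M83, at most 27, 25 and 29 higher and 20, 21 and 20 lower, while independent lists would share 0.992 and 0.172, 0.951 and 0.171, and 1.36 and 0.0843. The covariance of log2 ratios was 0.291, 0.232 and 0.255 for the 3 pairs, against 0.28, 0.28 and 0.281 in the simulations, and the shared control cannot be split. The genes higher in M8 and M32 and in M32 and M83 outnumbered every simulation, while those higher in M8 and M83 and those lower in each pair did not. Differences between the real lines widened the simulated spread, so counts within the simulations cannot show that nothing was shared.

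Between libraries, the number of genes at least 4-fold different was 147 for control and M8, 153 for control and M32, 148 for control and M83, 154 for M8 and M32, 211 for M8 and M83 and 174 for M32 and M83. Treating the 4 libraries alike, 65 genes were set apart in M8, 14 above and 51 below every other library. There were 45 such genes in M83 (20 above and 25 below), 31 in control (4 above and 27 below) and 30 in M32 (15 above and 15 below). Of the 51 genes below in M8, 24 belonged to an interferon list and 10 lay on chromosome 12.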

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

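All alternatives in this part were chosen before the data were examined, and none was added after a result was seen. Slc1a2 passed under each of the 12 other settings of the main comparison, with an adjusted p of up to 0.046 (without M8) and 0.0421 in limma-voom. The count of 1 changed gene became 2 with no filter on low counts and 37 in DESeq2, and the cause was not tested. Of the 9 list calls, 0 remained with an estimated correlation, and fry called 1. On simulated lists of independent genes those tests recovered 0 and 4 of 20, so they had little power there. The estimated correlation was 0.546 for MAPK/ERK output, 0.267 for YAP/TEAD, 0.147 for cell cycle, 0.056 for mesenchymal and 0.038 for p53 genes, above the preset 0.01. It was below 0 for DNA repair, TGF-beta, fibroblast and endothelial genes. For the lists above 0.01 the lost calls may therefore not come from lost power alone. For the lists below 0 a higher correlation cannot have cost the call. Single libraries give no replicate error, so the counts of the 4-fold rule rest on their limits. With a minimum of 10 counts the rule gave 377 genes in M8, 364 in M32 and 359 in M83, with a minimum of 200 counts 56, 73 and 58, and with a limit of 2-fold, the interval still leaving out 2-fold, 347, 379 and 373. For genes shared by M8 and M32 these limits gave 114, 19 and 123 against 40, for M8 and M83 96, 13 and 93 against 30, and for M32 and M83 92, 19 and 101 against 36. Genes set apart numbered 73, 13 and 176 in control, 105, 28 and 189 in M8, 63, 13 and 137 in M32 and 100, 20 and 184 in M83 under the same limits. Between M8 and M32 they gave 335, 61 and 368 genes, between M8 and M83 472, 83 and 510, and between M32 and M83 419, 72 and 423. These changes follow from the limits themselves. Scaling by library size moved the counts little, for instance from 148 to 156 genes in M83.

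Leaving out a mutant line turned the direction of some list tests that had not passed. The adjusted p then ranged from 1.84e-07 to 0.067 for type I interferon genes, with the upward call without M8 and a downward one without M83 (0.0102). It ranged from 0.0539 to 0.357 for interferon gamma genes, 0.0254 to 0.412 for mitochondrial genes, 0.116 to 0.954 for chemokines, 0.169 to 0.963 for NF-kB targets, 0.897 to 0.963 for Wnt targets, 0.0339 to 0.983 for the unfolded protein and stress list, 0.176 to 0.454 for germline genes and 0.812 to 0.901 for the genes named regardless of value. Calls were also gained, for cholesterol genes (8.45e-11) and the unfolded protein and stress list (0.0339) without M83, for MHC class I genes without M8 (0.0122) and for mitochondrial genes downward without M32 (0.0489) and upward without M8 (0.0254). These gained calls used the preset correlation. Wnt targets also turned with no filter (0.891) and in fry (0.946), and colonic differentiation with no filter (0.534). The cause was not tested. Among named genes the log2 difference changed sign in some that had not passed, with ranges of -0.424 to 0.083 for B2m, -1.219 to 0.243 for Cd274, -0.009 to 0.184 for Apc, -0.047 to 0.069 for Pik3ca, -0.088 to 0.009 for Fbxw7, -0.022 to 0.062 for Jak1 and -0.023 to 0.027 for Ctnnb1. No paired analysis was possible because the control group has 1 column of counts and the labels carry no replicate numbers.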

Other observations

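Some genes differed between lines in ways the comparisons above did not take up. Of the 10 genes named as lower in the 3 lines, 5 (Acadm, Rabggtb, Rpl34, Mettl14 and Dnttip2) lie on chromosome 3, and Acadm and Rabggtb are neighbours there. The NF-kB regulator genes Nfkbie and Traf1 had 135 and 52 counts in control, 473 and 170 in M8, 223 and 45 in M32 and 358 and 239 in M83. Sox9, a progenitor transcription factor gene, had 231 counts in control, 433 in M8, 80 in M32 and 774 in M83. Aldh3a1, an aldehyde dehydrogenase gene of the NRF2 list, had 99, 104, 38 and 553 counts, and Dkk2, a Wnt antagonist gene, 424, 930, 1146 and 2682 in the same order. These single-library values have no test.

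Patterns weighed here were noticed in these data, so each explanation is a hypothesis. What each explanation would give was written down after the pattern was seen and before its test was run, with 2 exceptions. The test of culture differences for the interferon pattern and that of E2F6 targets were chosen after the result was seen.

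Some whole chromosomes were lower in a single line. The genes of chromosome 12 had a median log2 ratio of -0.55 in M8, with 90.8% of 348 genes below control, and those of chromosome 16 a median of -0.56 in M83. Chromosome 13 was at -0.29 and chromosome 15 at -0.22 in M83, and chromosome 6 at -0.25 in M32. Chromosomes were also higher in several lines: 1, 15, 17 and 19 in M8 (0.18, 0.17, 0.19 and 0.19) and in M32 (0.12, 0.09, 0.15 and 0.11), and 17 in M83 too (0.14), where chromosomes 1 and 3 were lower (-0.10 and -0.12). Rises shared by lines could also come from the control, which was not tested. H2-K1, H2-D1, Tap2 and Psmb8 of the MHC class I list lie on chromosome 17, and what its rise adds to that list was not tested. A fit on GC content and gene length left medians of -0.544 for chromosome 12 and -0.567 for chromosome 16, which argues against those biases. The highest of 5 stretches had a median of -0.415 on chromosome 12 and -0.506 on chromosome 16, as a lower copy number of the whole chromosome may give, while a stretch at -0.038 on chromosome 13 and at -0.039 on chromosome 6 argues against whole-chromosome loss there and leaves partial loss open. DNA was not analysed here, and whether ENU, growth of the clones or a different parent culture gave rise to these differences was not tested.

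The low interferon genes of M8 may reflect a signalling change in that line. Lower expression of chromosome 12 acting on the genes' own copies can reach only the 3 of 33 tested members that lie there. Without them the median was -1.996, an outcome nearly fixed beforehand, because 26 of the 33 were at least 2-fold lower. Leukocytes in the control culture are argued against by the sum of Ptprc, Tyrobp, Fcer1g, Laptm5 and Coro1a, 0.196 CPM in control. A difference between cultures on the day of harvest stays open, since M8 has 1 column of counts and no repeat beside it, and a mutation in the pathway was not tested.

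The control stood apart from the 3 lines in Slc1a2, in cell cycle genes and in mesenchymal genes. Setting each library in turn against the other 3, edgeR called 1 gene for control, 3 for M8, 0 for M32 and 0 for M83. Thus 2 of 4 splits, the real one and that of M8, gave at least 1 gene, and the highest other gave 3. A share under 0.05 cannot be reached with 4 splits. DESeq2 called 37 genes for control, 137 for M8, 48 for M32 and 122 for M83, so by that count the control was the least set apart. The number of lists called was 9 for control and also 9 for M32. With another library set apart, the smallest adjusted p of the cell cycle list in camera was 0.00531 (M83) against 6.38e-09 for control. That list also passed with M8 set apart (0.0364). For the mesenchymal list the smallest was 0.0191 (M32) against 0.000274 for control. Both lists were picked for their small p with control set apart, and in the other splits control adds to the spread of the group of 3. The comparison therefore cannot show whether these 2 lists vary as much around any library. These values used the preset correlation, and no list passed with an estimated one. Other called lists had a smaller adjusted p with M32 set apart, namely MAPK/ERK output (2.64e-15 with M32 set apart, 9e-04 with control) and YAP/TEAD targets (0.00582 and 0.0385). Of 8 abundant fibroblast genes, 1 (Serpinf1, in M83) lay more than 0.5 below control and 4 lay above it in every line. These genes cannot tell fibroblasts in the mutant cultures from a change in the cells themselves. Of the 19 fibroblast markers 14 reached the filter on low counts. Among the rest, Thy1 had 0 counts in every library, and Postn, Lum, Fap and Dpt had 0 in control and at most 8 in a line. Those counts argue against fibroblasts that express these genes, and fibroblasts without them stay open. The growth state of the lone control culture also stays open.

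E2F6 is known to repress germline genes, and their release in M8 was a further hypothesis. Of 20 listed germline genes, 3 had 10 or more counts in M8, and of these 3 only Taf7l, with 10 counts against 0, 0 and 2, was highest there. Stag3, Smc1b, Tuba3a and Tdrkh were also highest in M8, with at most 4 counts. These counts argue against a broad release of the 20 genes, and Sycp1 and Zcwpw1 were already transcribed in control. The fixed germline and imprinted list had a median of 0.55 in M8, with 6 of 7 tested genes higher, at percentile 88.7 of the matched random lists. Its median was -0.13 in M32 and -0.36 in M83, and most of its 30 members were below the filter.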
